A study of Mus musculus with 4 samples.

How the data were processed

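The 4 libraries are bulk ATAC-seq of the iMGT-Myh6-eGFP-MEF line, 2 with siControl and 2 with siChst7. Per the labels' protocols, cells were plated at 500000 per plate and transfected the day before induction, MGT was induced with doxycycline at 1 μg/mL, and cells were frozen at day 1, with about 250000 cells per condition, tagmented with a commercial kit after thawing, and sequenced with paired reads of 75 bp to a target of 50 M reads per library. The submitters' processing notes name Bowtie, SAMtools, MACS3, bedtools and HOMER and the build mm10, without versions, order or roles. The read numbers reached, duplicate removal, mitochondrial read removal, the shift of Tn5 cut sites and the use of an exclusion list are not given in the sources used here. In every library the peak with the highest −log10 q, between 8517 and 9381, lay on chromosome 2 and ended at 98667313.

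The deposited files are peak lists, 1 per library, and the peak names refer to a single sorted alignment each, so peaks were called per library and replicates were not pooled. The score deposited with each peak is 10 times its −log10 q, as a whole number. The fold enrichment deposited by the authors is a ratio of the pileup at the summit to the local background within that library. The −log10 p and −log10 q deposited by the authors are those of the summit, and the lowest −log10 q per library lies just above 2, so that peaks were listed at a q-value of at most 0.01. These are the authors' values per peak; they were used to describe, rank or filter peaks within a list and never to test a difference between libraries. The summit offset deposited with each peak was used for the summit windows.

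Read totals are unknown from these files. Peaks with a −log10 q under 8 gave a relative depth: in each library 33.1% to 45.8% of these peaks had a fold enrichment on whole multiples (within 0.001 reads) of a constant step, which MACS gives for whole fragments over the genome-wide background with a pseudocount, and for 99.3% to 99.8% of those the Poisson p at that background matched the deposited one within 0.02 on the −log10 scale. The background pileup was 1.92 and 1.82 in siControl and 2.03 and 1.48 in siChst7. Divided by the narrowest peak of each library (183, 180, 189 and 187 bp), taken as the fragment length used by the caller, it gave the relative read densities. For a test of depth, the reads under each summit and the local background were solved from the deposited fold enrichment and p, the reads of the other 3 libraries, at peaks with a −log10 p under 100, were thinned at random to the read density of siChst7 replicate 2 in 20 draws, and peaks whose −log10 p fell below 3.88, the lowest of that library, were dropped.

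Peaks on chromosomes 1 to 19, X and Y of the 4 libraries that shared at least 1 bp were merged into regions. Peaks on unplaced sequences (58 to 73 per library) and the mitochondrial genome (4 per library) were left out. A region is called siChst7-specific when both siChst7 libraries and neither siControl library hold a peak in it, and siControl-specific in the reverse case. Counts were set beside those of the 2 other splits of the 4 libraries into 2 and 2. Jaccard indices compare covered bases. Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly of mm10, with 21883 protein-coding genes on these chromosomes; 456 of the 457 genes on the 23 lists matched. The table holds no strand and no exons, so distances were taken to the nearer of the 2 ends of a gene, in place of the transcription start sites foreseen in the design, and exons and introns are not told apart. Whether the group-specific regions differ in transcription factor motifs, and whether coding exons of Mef2c, Gata4 and Tbx5 show reads from the inducible copies, was not analysed here, as both need a sequence or exon annotation not used here.

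Gene lists, gene ends (within 1 kb) and chromosomes were compared between siChst7-specific and siControl-specific regions with two-sided Fisher's exact tests on regions, with Benjamini-Hochberg adjustment within each family; regions are not replicates, so these tests compare 2 lists of regions of these libraries. A region belonged to a list when its nearest gene end lay within 100 kb and the gene was on the list, and lists with fewer than 5 group-specific regions were counted and not tested. Odds ratios carry 0.5 added to each cell, except with the replicate number as a block, where they are Mantel-Haenszel odds ratios without it. Shares have exact 95% binomial intervals, which cover counting error only. The share of a list's genes with a peak at a gene end in all 4 libraries was set against all other protein-coding genes with the same test.

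The gene lists, the tests on group-specific regions, their alternatives and the rule for named genes were fixed before the data were examined; the tests of gene ends in all 4 libraries, the counts of genes with an end peak in only 1 group and the excess ratio of the splits were added afterwards. The rule names Chst7, Mef2c, Gata4, Tbx5 and Myh6, then per direction the 8 group-specific regions with the highest worse of their 2 within-library percentile ranks of −log10 q, then up to 2 regions per list and direction by the same rank, each by the nearest gene within 100 kb; predicted genes are passed over. A region that the rule selects for the skeletal muscle list is not reported here. Genes named as examples of lists with accessible ends, and Celf2 and Ccdc63, each as the gene around a region, were chosen after their values were seen. So were the regions given as examples where the 2 siRNAs are first compared, taken from those the rule names. The alternatives were a −log10 q of at least 5, lists of equal length (66103 peaks), autosomes only, each library left out and summit windows of 200 bp. Further ones were an overlap no shorter than the part of the shorter peak outside it, looser and stricter rules for presence, the replicate number as a block, and other gene distances. A minimum peak width of 200 bp, gene bodies in place of gene ends, and the alternatives of the gene-end shares were added after the data were examined. The functions were tested on simulated data: all 2000 planted regions and all 286 planted group-specific ones were found. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.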

Results

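Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in the iMGT-Myh6-eGFP-MEF line. This is a mouse embryonic fibroblast line in which doxycycline switches on the cardiac transcription factors Mef2c, Gata4 and Tbx5 (MGT), and whose name carries an eGFP reporter of the cardiac myosin gene Myh6. Cells received either a control siRNA (siControl, 2 libraries) or an siRNA against Chst7 (siChst7, 2 libraries), a carbohydrate sulfotransferase of chondroitin sulfate synthesis. All 4 libraries were taken at day 1 after MGT induction. By its title the series is about how fibroblasts keep their identity when they are reprogrammed towards heart cells, and the comparison asks which accessible regions differ between the 2 siRNAs. The deposited lists held 73902 and 75696 peaks in siControl replicates 1 and 2, and 74402 and 66165 peaks in siChst7 replicates 1 and 2. Relative to siControl replicate 1, the background read density recovered from the fold steps was 0.964 in siControl replicate 2, 1.02 in siChst7 replicate 1 and 0.757 in siChst7 replicate 2. On chromosomes 1 to 19, X and Y the peaks merged into 90239 regions. The labels call the replicates biological but do not say whether they were separate cultures, so any difference is measured against the spread between these samples only.

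The Chst7 gene itself had an accessible region near its start coordinate in every library. That region lay at X, 20059156 to 20060692, inside Chst7 (X, 20058963 to 20099991, mm10) and 0.193 kb from the gene end. The authors' fold enrichment at it was 15.04 and 13.1 in siControl, and 12.0 and 12.0 in siChst7, each a value of that library's own list. A second region at 20077762 to 20078178 was also called in all 4 libraries, and 2 weaker ones were each called in a single library. An siRNA acts on the transcript, so accessibility at Chst7 does not check the label, and knockdown was not measured here. Of the 3 reprogramming factors, Mef2c held 7 regions within its body and 5 kb flanks, 6 of them called in all 4 libraries. Gata4 held 8 regions, 6 of them in all 4, and the one at 14, 63244745 to 63245744 had the highest fold enrichment in each of 3 libraries, at 12.3 and 11.9 in siControl and 13.2 in siChst7 replicate 2. Tbx5 held a single region called in all 4 libraries, at 5, 119882938 to 119883491, 1.73 kb inside the gene's end, with fold enrichments of 22.6, 23.0, 22.2 and 19.7. Both regions of Myh6, which encodes the alpha myosin heavy chain of heart muscle, were called in all 4 libraries, including the one over the gene end at 14, 54966521 to 54968799. Whether DNA of the Myh6 reporter adds to these peaks was not tested. None of the regions at these 5 genes was called in both libraries of one siRNA and neither of the other. Whether reads from the inducible copies of Mef2c, Gata4 and Tbx5 add to the peaks at these genes was not tested.

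**Figure D1:**
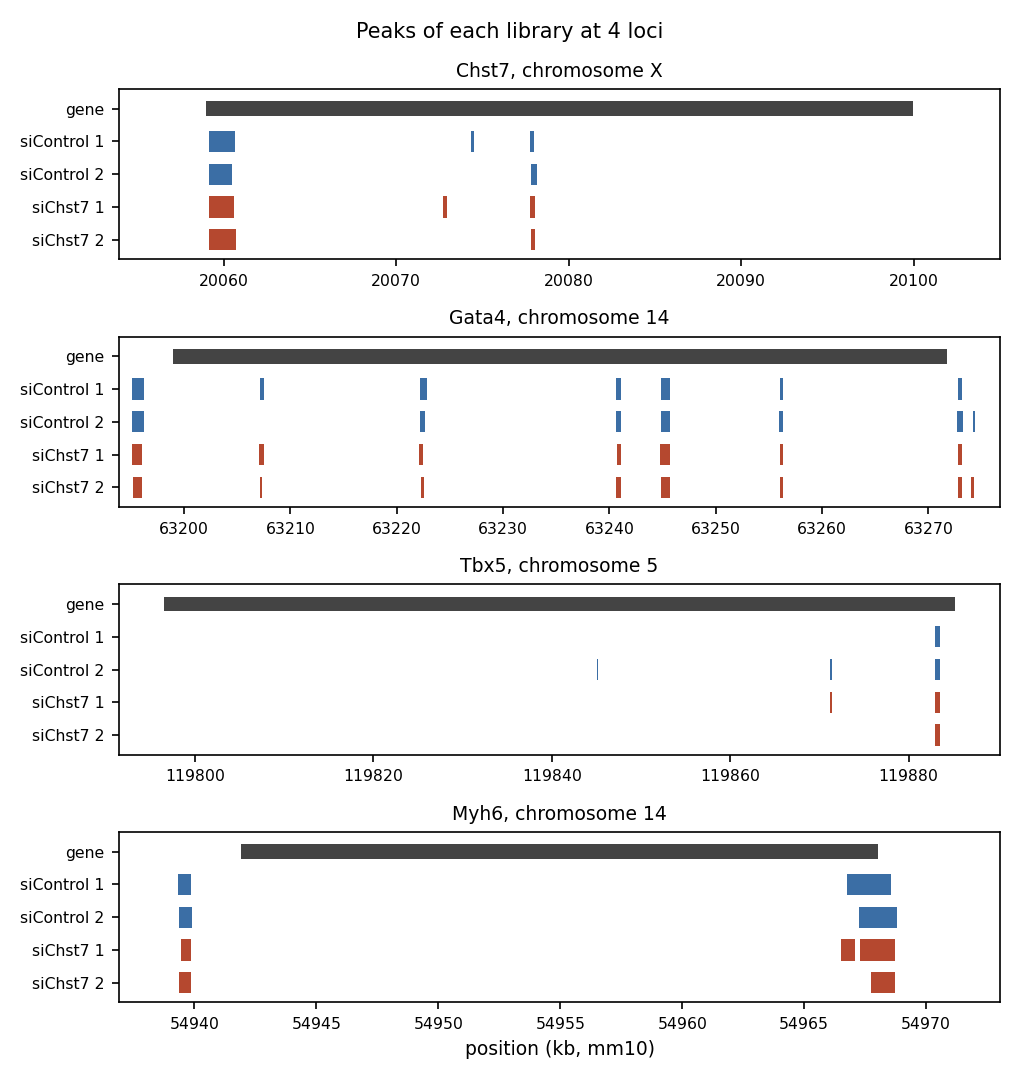
Peaks of each library over Chst7, Gata4, Tbx5 and Myh6 with 5 kb flanks, by position in kb (mm10). Dark bars are genes, blue bars siControl peaks and red bars siChst7 peaks; the regions of Myh6 and the region at the start coordinate of Chst7 appear in all 4 libraries.

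In all 4 libraries, genes of YAP and TEAD, the cell cycle, AP-1 and glycosaminoglycan synthesis mostly had a peak at a gene end, and most cardiac transcription factor genes had none. Every one of the 16 YAP and TEAD genes, members and targets of the Hippo pathway such as Yap1, Tead1 and Ccn2, had a peak within 1 kb of a gene end in all 4 libraries. So did 23 of 25 cell cycle genes, 11 of 12 AP-1 genes such as Fosl1 and Jun, and 32 of 39 genes of glycosaminoglycan synthesis and sulfation, among them Chst7, Chst11 and Ext1. Of the 21 cardiac transcription factor genes 5 did, namely Tbx2, Tbx3, Gata6, Mef2d and Ppargc1a, whereas Nkx2-5, Hand2 and Tbx20 had none in any library. Fibroblast genes stood above cardiac genes, with 37 of 52 (71.2%) matrix and identity genes, such as Col1a1, Postn, Thy1 and Twist1, against 39 of 82 (47.6%) cardiac genes, such as Tnnt2, Myh6 and Nppa (odds ratio 0.375, Fisher's exact p = 0.00783 over genes, two-sided). This contrast rests in part on the transcription factor list: without it 34 of 61 cardiac genes (55.7%) had such a peak. The difference kept its direction but was smaller and, over fewer genes, no longer past the threshold (odds ratio 0.519, exact p = 0.119). Over all 21883 protein-coding genes the share was 53.8%. Only the 2 outermost ends of each gene were looked at, so a gene without a peak there is not thereby closed. Mef2c and Gata4 counted among the genes with none, yet held regions called in all 4 libraries elsewhere. The housekeeping gene Ywhaz and the fibroblast genes Col3a1 and Pdgfra, picked after their values were seen, also had none in any library.

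Against all other protein-coding genes, 7 of the 23 lists had a higher share and 2 a lower one (two-sided Fisher's exact tests, Benjamini-Hochberg over 23 lists). By these exact tests the higher ones were YAP and TEAD genes (adjusted p = 0.000711), cell cycle (adjusted p = 0.000711), glycosaminoglycan synthesis and sulfation (adjusted p = 0.00236), AP-1 factors (adjusted p = 0.0371), TGF-beta and BMP signalling with 19 of 24 (adjusted p = 0.0410), inflammation and interferon with 19 of 24 (adjusted p = 0.0410), and housekeeping genes with 13 of 15 (adjusted p = 0.0422). The lower ones by the same exact tests were cardiac transcription factors (adjusted p = 0.0371) and cartilage and bone with 4 of 17 (adjusted p = 0.0410). Fibroblast matrix genes, with 19 of 25, did not pass (adjusted exact p = 0.0586), nor did fibroblast identity genes with 18 of 27. The sarcomere genes (13 of 25), cardiac ion handling (11 of 20) and cardiac metabolic and secreted genes (10 of 16) did not pass either. Markers of other cell types were at 12 of 15 for smooth muscle and myofibroblasts, 8 of 21 for skeletal muscle, 7 of 18 for neural cells, 5 of 15 for endothelium, 3 of 14 for epicardium and epithelium, 5 of 13 for immune cells and 2 of 9 for adipocytes, none of which passed. Wnt signalling genes stood at 13 of 22 and proteoglycan and hyaluronan genes at 12 of 23. With a window of 2.5 kb the lower lists fell to 0 and the higher ones to 5; Gata4, for example, has a region called in all 4 libraries at 1.02 kb from its end. This comparison of lists was chosen after the data were examined, and without siChst7 replicate 2 the higher lists numbered 3.

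**Figure D2:**
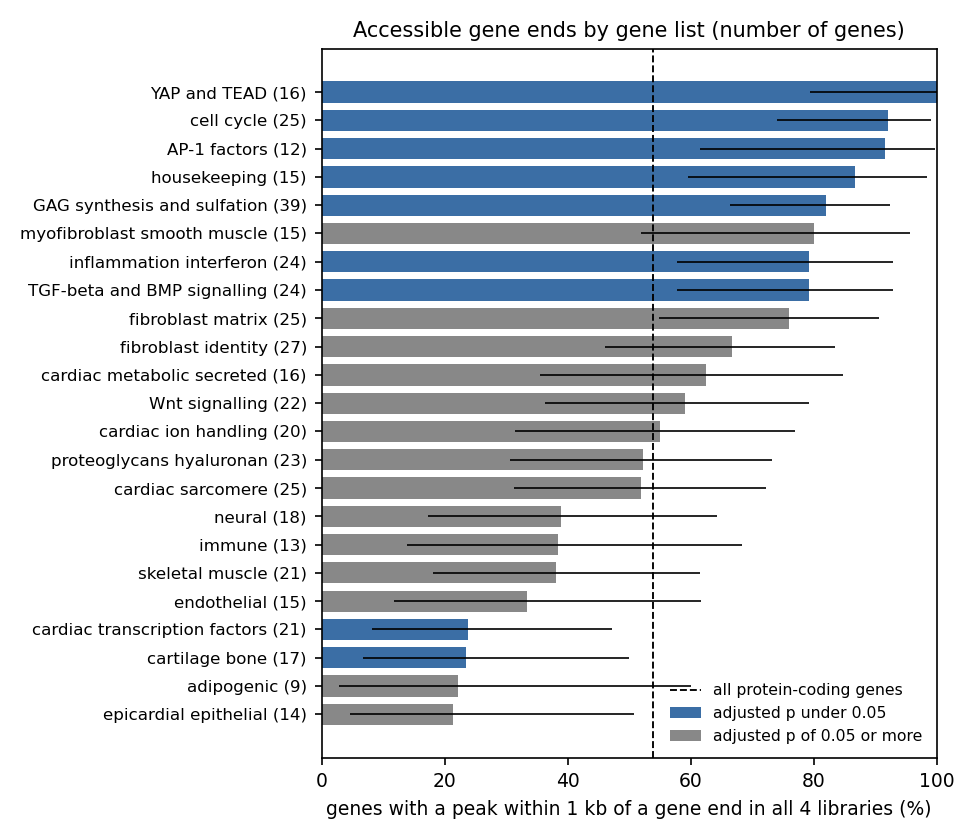
Percent of each list's genes with a peak within 1 kb of either gene end in all 4 libraries, with exact 95% binomial intervals and the number of genes in parentheses. The dashed line marks the 53.8% of all protein-coding genes; YAP and TEAD genes reach 100% and cardiac transcription factors 23.8%.

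Between siChst7 and siControl, 1122 regions were called in both siChst7 libraries and neither siControl library. In the reverse case, 2562 were called in both siControl libraries and neither siChst7 library. The siChst7-specific regions included sites inside Lamc3, a laminin chain, inside the cardiac genes Myom1 and Cacnb2 and inside the fibroblast gene Ddr2. The siControl-specific regions included sites inside the cardiac genes Jph2, which ties the sarcoplasmic reticulum to the T-tubule, and Kcnq1, and inside the fibroblast gene Col5a1. These examples were taken because their calls also held under each of 3 filters. The filters were a −log10 q of at least 5, equal list length and peaks of at least 200 bp. No gene list passed a test of its share between the 2 sets, and 55924 regions (62.0%, exact 95% interval 61.7 to 62.3) were called in all 4 libraries. The group-specific regions were weak, with a median −log10 q of 6.52 (siChst7-specific) and 7.70 (siControl-specific) against 34.9 for regions called in all 4.

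The highest-ranked siChst7-specific region lay at 7, 25304744 to 25305113, 0.387 kb outside Tmem145, with the authors' −log10 q of 52.1 and 44.8 in siChst7 replicates 1 and 2. It was followed by regions 16.96 kb from the phospholipid scramblase gene Ano6 (15, 95773609 to 95773879), inside Ccdc124 (8, 70869547 to 70869786), 8.36 kb from the carboxylesterase gene Ces1a (8, 93011472 to 93011851), inside Lamc3 (2, 31917577 to 31918002), 5.98 kb from Mgme1 (2, 144287209 to 144287441), at 12, 112309675 to 112309985 with no gene end within 100 kb, and inside Rnf130 (11, 50114471 to 50114735). Among siControl-specific regions the highest was inside Il31ra, the interleukin-31 receptor, at 13, 112578164 to 112578352, with −log10 q of 1134 and 1118. The next lay inside Celf2 (2, 7076207 to 7076392), inside Mphosph8 (14, 56693996 to 56694178), 17.6 kb from Trim43b (9, 89066811 to 89067002), inside Atp8a2, a phospholipid flippase (14, 60016015 to 60016355), inside the hexokinase gene Hk2 (6, 82751878 to 82752106), over an end of Skil, a repressor of TGF-beta signalling (3, 31094976 to 31095160) and 4.16 kb from the transcription factor gene Sox4 (13, 28957860 to 28958076). Of these 8 siControl-specific regions, 5 held a peak narrower than 189 bp in at least 1 library, 189 bp being the width of the narrowest peak listed for siChst7 replicate 1. This cut comes from a siChst7 library, so siChst7-specific regions could hardly fall under it. With peaks of at least 200 bp in every library, the regions at Il31ra, Celf2, Mphosph8, Trim43b, Skil and Sox4 were no longer called in either group. Those at Ano6, Rnf130 and Hk2 were called in only 1 library.

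Regions near cardiac genes were found on both sides. The 4 cardiac lists together held 13 siChst7-specific regions (1.16% of them) and 15 siControl-specific regions (0.585%), an odds ratio of 2.00 with a 95% interval of 0.961 to 4.16 (Fisher's exact p = 0.0964). In the 2 other splits of the 4 libraries into 2 and 2, the same odds ratio was 2.57 and 0.693. Called with siChst7 only were, among others, regions inside Myom1 (17, 71090973 to 71091205), 4.19 kb from Xirp2, inside Cacnb2, inside Gja5 and inside Corin, 15.3 kb from Hopx, 16.1 kb from Nppb, and at 14, 63317508 to 63317726, 45.8 kb from Gata4. Called with siControl only were, among others, regions 1.85 kb from Myl2 (inside Ccdc63), 13.4 kb from Tpm1, and inside Jph2 (2, 163392549 to 163392821) and Kcnq1. Others on that side lay 15.3 kb from Gata5, 67.6 kb from Ppargc1a, 62.8 kb from Ppara and 59.1 kb from Ankrd1. Of these, the regions at Gata4, Gja5, Hopx, Tpm1 and Gata5 lost their call under at least 1 of the 3 filters. The sarcomere list had 4 siChst7-specific and 3 siControl-specific regions, ion handling 3 and 4, cardiac transcription factors 2 and 4, and metabolic and secreted genes 4 and 4. Of all peaks, those near sarcomere genes made up 0.163% ± 0.00748 in siControl and 0.169% ± 0.00292 in siChst7, those near ion handling genes 0.153% ± 0.00447 and 0.159% ± 0.00195, those near cardiac transcription factor genes 0.162% ± 0.000843 and 0.160% ± 0.00518, and those near metabolic and secreted genes 0.0930% ± 0.00127 and 0.0967% ± 0.00407 (SD, n = 2 each).

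Regions near fibroblast genes numbered 6 siChst7-specific and 12 siControl-specific (odds ratio 1.19, 95% interval 0.459 to 3.07, Fisher's exact p = 0.800), an interval that leaves room for an imbalance in either direction. Those called with siChst7 included regions inside Fbn1 and Ddr2, 38.2 kb from Fn1 and 2.57 kb from Ly6a. Those called with siControl included regions inside Col5a1 (2, 27969242 to 27969604), 17.02 kb from Loxl1, 58.3 kb from Twist2 and 78.4 kb from Pdgfra. The regions at Fbn1 and Fn1 lost their call under each of the 3 filters. Peaks near fibroblast matrix genes made up 0.290% ± 0.00552 of siControl peaks and 0.289% ± 0.00276 of siChst7 peaks (SD, n = 2 each), and those near fibroblast identity genes 0.256% ± 0.00149 and 0.258% ± 0.00324 (SD, n = 2 each). The smooth muscle and myofibroblast list had 0 and 3, with Synpo2 and Myh11 among the latter.

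Genes of the pathway of Chst7 were represented on both sides as well. Glycosaminoglycan synthesis and sulfation had 2 siChst7-specific regions, at the chondroitin sulfotransferase gene Chst12 (3.36 kb away) and inside the heparan sulfate polymerase gene Ext1, and 7 siControl-specific ones, among them regions inside Chst11 and 14.4 kb from Sulf2. Proteoglycans and hyaluronan had 5 and 8, with Sdc1 and Gpc4 on the siChst7 side and Gpc1 and Vcan on the siControl side. TGF-beta and BMP signalling had 3 and 8, with Smad6 on both sides and Smad7 on the siChst7 side. Wnt signalling had 3 and 9, with Tcf7l2 and Lrp6 against Ror2 and Sfrp1. YAP and TEAD had 0 and 5, 2 of them named here near Tead1. AP-1 factors, adipogenic and housekeeping genes had none on either side. Inflammation and interferon had 2 (Il1a, Nfkb1) and 1 (Ptgs2), cell cycle 0 and 2 (Cdkn2a, Ccne1), skeletal muscle 1 (Six4) and 3 (Myog among them), neural 2 (Snap25, Slc17a6) and 3 (Dcx and Map2 among them), endothelial 0 and 3 (Kdr and Lmo2 among them), epicardial and epithelial 0 and 2 (Grhl2, Bnc1), immune 0 and 1 (Itgam), and cartilage and bone 1 (Pth1r) and 4 (Ihh and Sox5 among them). Of the regions named for these lists, those at Ext1, Gpc4, Gpc1, Smad6 (the siChst7 side), Smad7, Lrp6, Tead1 (one of them), Nfkb1, Ptgs2, Cdkn2a, Ccne1, Six4, Snap25, Slc17a6, Dcx, Map2, Lmo2, Grhl2, Bnc1, Itgam, Pth1r, Ihh and Sox5 lost their call under at least 1 of the 3 filters. Of the 13 lists with at least 5 group-specific regions, 0 passed the two-sided Fisher's exact test with Benjamini-Hochberg adjustment (lowest adjusted p = 1), and 0 had an unadjusted p under 0.05 (lowest 0.210). In simulated data a planted odds ratio of 4 in the proteoglycan and hyaluronan list, which has the most group-specific regions (13), was called in 37% of 100 simulations and an odds ratio of 16 in 96%, so shifts of the smaller size could be missed in every list.

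**Figure D3:**
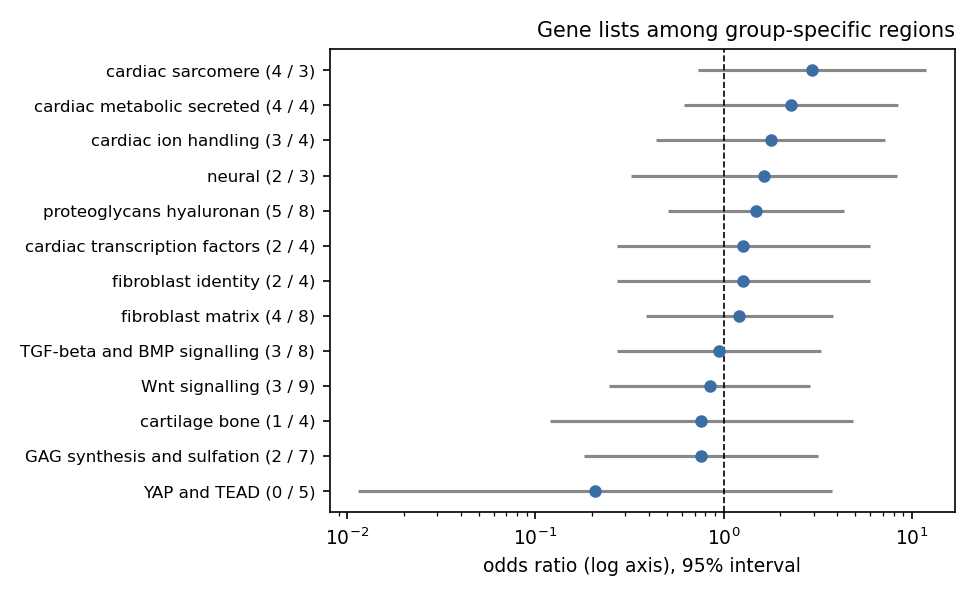
Odds ratio of each tested gene list among siChst7-specific over siControl-specific regions (points, log axis) with 95% intervals (bars); numbers in parentheses are siChst7-specific and siControl-specific regions. The intervals of all 13 lists include 1, from 0.207 for YAP and TEAD to 2.94 for the sarcomere.

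siChst7-specific regions lay at gene ends less often than siControl-specific regions: 55 of them (4.90%, exact 95% interval 3.71 to 6.33) and 198 of the others (7.73%, 6.72 to 8.83) were within 1 kb of an end of a protein-coding gene, against 22.0% of the regions called in all 4 libraries. The odds ratio was 0.619 (two-sided Fisher's exact p = 0.00178 over regions, which are not replicates). With 200 bp windows around peak summits in place of whole peaks the direction turned (odds ratio 1.14, exact p = 0.205). The difference was no longer past the threshold without siControl replicate 1 (odds ratio 0.849, exact p = 0.0765) or with a −log10 q of at least 10 (odds ratio 0.690, exact p = 0.435). Of the 2 other splits, the one that sets siControl replicate 2 and siChst7 replicate 1 against the rest gave 0.701 (exact p = 0.0401) and the one by replicate number 1.12 (exact p = 0.517), so a difference of this kind also arose in a split not made by siRNA. By chromosome, 0 of 20 tested chromosomes passed (lowest adjusted p = 0.295, Fisher's exact tests), and 2 had an unadjusted p under 0.05.

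The number of group-specific regions was 3684 (4.08% of all regions), against 2606 and 2853 in the 2 other splits of the 4 libraries. Regions called in exactly 2 libraries numbered 1122 for the siChst7 pair and 2562 for the siControl pair, and between 677 and 2176 for the pairs of different siRNAs. The share of siChst7-specific among group-specific regions was 30.5%. In each of the 2 other splits, the side holding siChst7 replicate 2 also had fewer regions. These were 837 against 1769 in the split by replicate number, and 677 against 2176 in the remaining one. An imbalance in that direction is therefore not particular to the split by siRNA. The siChst7-specific share was 48.9% when each library was held to its 66103 strongest peaks, a setting that itself draws the share towards an even balance. It was 58.9% without siChst7 replicate 2 and 29.2% without siChst7 replicate 1, both under a rule that then asks for a peak in 1 siChst7 library but in 2 siControl libraries. The Jaccard index of covered bases was 0.728 for the siControl pair and 0.706 for the siChst7 pair, and 0.711 ± 0.0110 for the 4 pairs of different siRNAs (mean ± SD), so that the mean within groups exceeded that between groups by 0.00683, less than the spread. Leaving out either siControl library turned this difference negative (−0.00166 and −0.00680). With 2 libraries against 2 there are 3 splits, and the smallest share of splits that an exact permutation can give is 0.333.

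**Figure D4:**
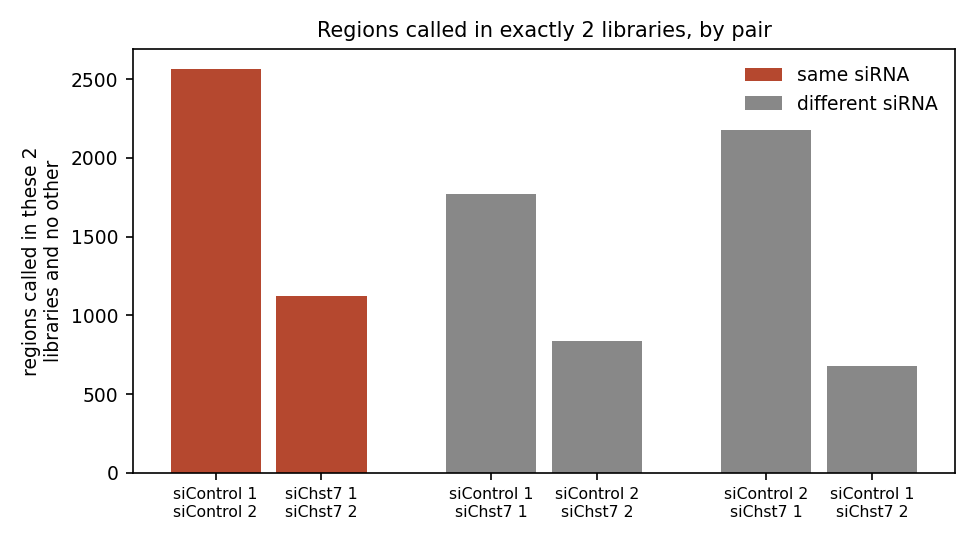
Number of regions called in exactly 2 libraries, for each of the 6 pairs of libraries, grouped by split of the 4 libraries into 2 and 2. Red bars are pairs of the same siRNA (2562 and 1122) and grey bars pairs of different siRNAs (677 to 2176).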

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

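The minimum peak width, gene bodies and all alternatives of the gene-end shares and of the excess ratio were chosen after seeing the data. The 1122 siChst7-specific and 2562 siControl-specific regions became 7613 and 11855 when presence in at least 1 library sufficed, 128 and 608 with a −log10 q of at least 10 in both, and 2639 to 5779 and 4035 to 7807 with a library left out, which follows from the looser or stricter rule. With lists of equal length the siControl-specific regions numbered 1632. The siChst7-specific share of 30.5% was 48.9% with equal list length, 34.0% with peaks of at least 200 bp, 33.2% with windows around summits, 39.1% with presence in at least 1 library, 17.4% with a −log10 q of at least 10, and 25.3% to 58.9% with a library left out, the highest without siChst7 replicate 2; equal list length draws this share towards an even balance, and a library left out makes the rule unequal between the groups. The Jaccard difference ranged from −0.00680 to 0.0271 with a library left out. The gene-end odds ratio of 0.619 was 1.14 with windows around summits and 0.690 (exact p = 0.435) with a −log10 q of at least 10, and 0.646 to 0.849 with a library left out, no longer past the threshold without siControl replicate 1; the cause was not tested. Chromosomes past the threshold numbered 0 to 2 with a library left out. No list passed under any of 15 alternatives; with a −log10 q of at least 10 no list had enough regions to be tested. Lists with a higher share of accessible gene ends numbered 3 to 7 and those with a lower share 1 to 3 with a library left out, and the latter 0 within 2.5 kb; fibroblast gene ends stayed above cardiac ones in all 9 alternatives, but without the cardiac transcription factors no longer past the threshold (odds ratio 0.519, exact p = 0.119). Genes with an end peak in siChst7 only numbered 34 within 2.5 kb and 63 to 134 with a library left out, and in siControl only 177 to 302. Of 79 named regions, 59 were still called in both libraries of their group and neither of the other at a −log10 q of at least 5, 52 with equal list length and 61 with peaks of at least 200 bp. No pairing by replicate number was seen in the peak calls (correlation of deviations −0.00466 over regions), which does not show how the samples were handled. With the replicate block there were 7361.5 and 11761.5 regions per pair, a siChst7 share of 39.0%, a Mantel-Haenszel gene-end odds ratio of 0.762 and 0 lists. The pairs behind this share went opposite ways. Between the replicates numbered 1 it was 52.0% (9536 siChst7-only against 8811 siControl-only regions). Between those numbered 2 it was 26.1% (5187 against 14712). The motif and coding exon tests and their alternatives were not run. Read totals are unknown, so how far depth limits the calls in siChst7 replicate 2, which has the lowest estimated read density, is not settled.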

Other observations

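At the level of whole genes, 20 genes had a peak within 1 kb of an end in both siChst7 libraries and neither siControl library, and 95 in the reverse case. With lists of equal length the counts were 27 and 66. They were 134 and 177 without siChst7 replicate 2, and 71 and 302 without siChst7 replicate 1. Without siControl replicate 1 they were 69 and 263, and without siControl replicate 2 they were 63 and 230. The siControl-only genes were more numerous in each of these, by differing margins. A library left out makes the rule unequal, as its group then needs a peak in only 1 library. With a siControl library left out this favours siControl-only genes, so those counts are no support for a surplus. Of the 456 list genes matched, 4 were siControl-only, namely Dcn (decorin) of the fibroblast matrix list, Ldb3 of the sarcomere list, Comp of the cartilage and bone list and Itgam of the immune list, and none was siChst7-only. The siChst7-only genes included Popdc2, which is expressed in heart muscle, the potassium channel gene Kcna1 and the chemokine receptor gene Ccr1. These names were picked after their values were seen. In the 2 other splits of the libraries the counts were 42 and 20, and 71 and 28, so neither 20 nor 95 was set apart by a test. The lower count was each time that of the side holding siChst7 replicate 2.

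In the patterns weighed here, the tests of per-library call rates and of other splits were chosen after the result was seen; the peak width filter, the depth test and the width comparison with the groups exchanged were added after the data were examined, the last after the siControl shares by width were known, with what each would show set down before its value was seen. The first pattern is the surplus of siControl-specific regions (2562 against 1122). With peaks of at least 200 bp in every library the siChst7 share was still 34.0%, which argues against the minimum peak width of the lists as its main source. In every split of the libraries, the side holding siChst7 replicate 2 had fewer regions: 1122 against 2562, 837 against 1769, and 677 against 2176. An imbalance in this direction thus came with that library whichever library it was paired with, and is not particular to the siRNA. What in that library gives it is not shown by these counts. A lower depth of siChst7 replicate 2 stays open: with the reads under each summit of the other libraries thinned to its read density, the siChst7 share was 32.0% (31.3 to 32.7 over 20 draws), below the 40% set down beforehand as speaking against depth, but that bound was wrong, as was seen afterwards. In every library fewer peaks lay within 1 unit of the lowest −log10 p than in the next unit (444 against 1491 in siControl replicate 1), so the lists are not limited by summit height alone, and thinning of summits leaves out peaks that become too narrow to be listed. After thinning, the other libraries still held on average 72354 (siControl replicate 1), 74381 (siControl replicate 2) and 72599 (siChst7 replicate 1) peaks. That is more than the 66103 of siChst7 replicate 2, so its shorter list was not reproduced. A loss of accessibility after siChst7 was not tested apart from depth.

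The second pattern is that the highest-ranked siControl-specific regions, such as those at Il31ra, Celf2, Mphosph8, Trim43b and Skil, were narrow. A minimum listed peak width that differs between libraries (183 and 180 bp in siControl, 189 and 187 bp in siChst7) may account for part of this, because peaks narrower than 189 bp could not be listed for siChst7 replicate 1; the regions at Il31ra and Trim43b each also held a siControl peak of 189 bp or more (189 and 192 bp), which could. The comparisons by width used only strong peaks, with a −log10 q of at least 10 in both libraries of the group. Of 12 regions with strong peaks under 189 bp in both siControl libraries, 58.3% (exact 95% interval 27.7 to 84.8) had no siChst7 peak, against 14.5% (11.8 to 17.6) of the 606 regions of 200 to 250 bp. The 57 regions of 189 to 200 bp, which could be listed for siChst7 replicate 1, lay between, at 26.3% (15.5 to 39.7), so the share fell with width by degrees and narrow peaks being missed in any library stays open. With the groups exchanged, 0 of 24 regions with strong peaks narrower than 200 bp in both siChst7 libraries lacked a siControl peak (0%, upper limit 14.2). Among strong siChst7 peaks of 200 to 250 bp the share was 5.47%, and the narrow regions are too few to decide. A biological difference at these loci was not tested.

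The third pattern is that the split by siRNA gave more regions called on one side alone (3684) than the other splits (2606 and 2853), although the siChst7 pair by itself, with 1122, held fewer than 2 of the mixed pairs (1769 and 2176). If each library had only its own call rate, the product of the 2 counts would be equal in the 3 splits. The excess ratio of the real split (the root of its product over the geometric mean of the other products) was 1.395 (95% interval 1.33 to 1.46, counting error only). Simulated libraries that differed only in an overall call rate gave 0.935 to 1.07, which argues against such call rates alone. Libraries that differ in how their calls depend on peak strength or width were not simulated. With peaks of at least 200 bp the excess ratio was 1.38, which argues against the minimum peak width. The real split was the 1 split of 3 with a ratio this high, and 3 splits are too few for a share under 0.05. The highest other ratio, 0.848, is no separate support, because by definition a high ratio in 1 split pulls the others down. A difference caused by the siRNA and one from handling each pair of libraries together may both give this, and the design does not part them.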
